A study of Mus musculus with 16 samples.

How the data were processed

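Microglia are the resident macrophages of the brain. They were sorted by flow cytometry from whole brains of mice labelled as knockouts of the DNA repair gene Ercc1 (KO) and of control mice (WT) at 6 and 12 weeks of age, on a mixed C57Bl6J and FVB background. The gate kept live cells with high CD11b, intermediate CD45 and no Ly6c. Bulk RNA was sequenced from 16 libraries, 4 in each of the 4 groups of genotype and age. Per the labels, libraries came from a low-input kit and were read on a NovaSeq instrument. Both 6-week groups held 2 males and 2 females, and both 12-week groups held 3 males and 1 female.

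The authors deposited raw counts per gene for each library, with an Ensembl identifier, a gene symbol and a count in each of 53700 lines. Counts were present for 29343 of these lines in at least 1 library, and 101 symbols occurred more than once. A deposited table for the whole series held counts for 36982 symbols, all equal to those per library (100%, exact match), and was used only for that check. The submitters' processing notes name FastQC 0.11.9, cutadapt 2.10, TopHat, SAMtools 1.10, Picard 2.13.2, HTSeq 0.11.0 and the mouse build GRCm39. The annotation release, the strand setting and the handling of reads that map to several genes are not given in the sources used here. Values of antisense genes and of genes with close copies are therefore uncertain. Gene positions are not given, because the annotation at hand belongs to another build.

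Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr by group and a minimum count of 10, which left 17090 genes. Library sizes were scaled by TMM, and levels are given as CPM on the scaled library sizes with mean and SD over 4 libraries, unless stated otherwise. A quasi-likelihood model with robust dispersion had a term for each of the 4 groups and a term for sex, and it was fitted to all 16 libraries at once. The common dispersion was 0.421, a biological coefficient of variation of 0.649. The 5 comparisons were KO against WT at 6 weeks and at 12 weeks, 12 against 6 weeks in KO and in WT, and the difference between the genotype effects at both ages. P values are two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are given with an approximate standard error, the absolute log2 change divided by the square root of the F statistic of the test. For genes with few counts in a group the log2 change depends on the prior, and this error is then unreliable.

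A group with no count for a gene was set to a floor of 3 counts over the group, and its fold is given as a lower bound. With 1 to 3 counts in a group, the ratio of the CPM is given with a counting interval at a confidence level of 0.95. Counting intervals and floors cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. With total counts between 7882182 and 22142972 per library, the floor of a single library lay between 0.135 and 0.381 CPM.

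Before the data were examined, 32 gene lists, the model, the alternatives to it and a rule for naming genes were fixed. The lists were written from general knowledge of microglia. They cover primed or disease-associated microglia, homeostatic microglia, interferon-stimulated genes, antigen presentation by MHC class I and by MHC class II, p53 targets, senescence-associated cell cycle inhibitors, inflammatory cytokines and NF-kB targets, proliferation, nucleotide excision and crosslink repair, TGF-beta and SMAD signalling, transcription factors of microglia and interferon, lysosome and phagocytosis, complement, cholesterol synthesis, lipid handling, glycolysis and hypoxia, nuclear genes of oxidative phosphorylation, oxidant production and NRF2 response, cytoplasmic ribosomal proteins, mitochondrially encoded genes, and immediate early genes. The other lists hold markers of border-associated macrophages, monocytes, neutrophils, T and NK cells, B cells, neurons, astrocytes, oligodendrocytes and their precursors, endothelial and mural cells, and erythroid cells. Each list was tested with camera at a preset correlation of 0.01 between genes, two-sided and adjusted over the 32 lists. The preset does not take up the correlation that genes of a list show in these libraries, and the p values depend on it. Camera with an estimated correlation was run beside it, and so was fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes.

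The naming rule took, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold with a mean of at least 5 CPM over the 16 libraries. For the 4 comparisons of groups, every library of 1 group also had to lie above every library of the other. Predicted genes, genes without a symbol, Xist, Tsix and genes of the Y chromosome were left out. Ercc1 and the 3 factors that the series title names, Irf7, Irf9 and Smad3, were added to every comparison, and up to 4 members with the smallest p were taken from each list described.

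Single values per library were compared by exact two-sided permutation over the 70 ways to divide 8 libraries into groups of 4, where the smallest possible p is 0.0286. Gene length and GC content came from a GENCODE annotation of the earlier build GRCm38 and were joined by Ensembl identifier for 17064 genes (99.8%). They serve as properties of genes and not as positions.

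Alternatives were DESeq2 1.42.0 with its own test, DESeq2 size factors within edgeR, no filter on low counts, no sex term, male libraries alone, a minimum fold of 1.5, thinning to the shallowest library, a fit on the compared libraries alone, a block on replicate number, and each library left out in turn. Chosen after seeing the data were a halfway sex code for 1 library, the removal of the 12-week WT libraries 3 and 8, single libraries left out of the gene length relation, of the lower bounds of folds and of the Ercc1 share, and the alternatives carried to the overlap between ages. The model was also tested on simulated data with planted changes. Pairs of libraries of the same group were checked for duplication, and the smallest chi-square per degree of freedom was 16.8. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. No library was left out of the comparisons.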

Results

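RNA was measured in microglia sorted from whole mouse brain in 4 groups of 4 libraries: WT and Ercc1 KO mice at 6 weeks, and WT and Ercc1 KO mice at 12 weeks. Ercc1 encodes a subunit of the endonuclease that cuts damaged DNA in nucleotide excision and crosslink repair, and the series title describes these mice as a model of accelerated aging. It names 3 regulators of microglia priming, the transcription factors IRF7, IRF9 and SMAD3. Total counts per library ranged from 8250645 to 13278797 in 6-week WT, from 9885121 to 17499408 in 6-week KO, from 9045823 to 22142972 in 12-week WT and from 7882182 to 9653663 in 12-week KO. Between 17249 and 21472 genes had a count in a library, and the 20 most abundant genes took 18.9% to 21.5% of its counts.

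The first principal component held 14.0% of the variance and had positive values in all 8 KO libraries and negative values in all 8 WT libraries. The 12-week WT replicate 3 stood apart on the second component, which held 10.3%, at -155, where 12-week KO replicate 4 was next lowest at -41.0. The 12-week WT replicate 8 at -133 and the 12-week KO replicate 4 at -72.5 stood apart on the third, which held 9.21%. Log2 CPM correlated between replicates with r from 0.894 to 0.914 in 6-week WT, from 0.871 to 0.899 in 6-week KO, from 0.814 to 0.865 in 12-week WT and from 0.833 to 0.869 in 12-week KO. The share of counts from mitochondrially encoded genes was 0.221% ± 0.0306 (SD, n = 4) in 6-week WT and 0.350% ± 0.0367 in 6-week KO. At 12 weeks it was 0.326% ± 0.0448 in WT and 0.567% ± 0.0855 in KO. Each of the 4 contrasts of genotype or age in this share separated the groups completely, with an exact permutation p of 0.0286, or 0.0762 after adjustment over 16 tests of library measures. Some tested genes had no count in any library of a group: 48 in 6-week WT, 50 in 6-week KO, 170 in 12-week WT and 111 in 12-week KO.

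Ercc1 (ENSMUSG00000003549) was lower in every KO library than in every WT library of the same age. At 6 weeks it stood at 2.82, 4.54, 4.05 and 3.10 CPM in KO replicates 1 to 4 and at 13.5, 15.98, 15.3 and 30.6 CPM in WT replicates 1 to 4. The KO mean of 3.63 ± 0.803 CPM (SD, n = 4) was 19.3% of the WT mean of 18.8 ± 7.91 CPM, with an exact permutation p of 0.0286, the smallest this design allows. At 12 weeks KO replicates 1 to 4 had 5.86, 0.425, 4.06 and 6.77 CPM, and WT replicates 3, 4, 5_6 and 8 had 7.46, 15.004, 11.2 and 49.2 CPM. The 12-week KO mean of 4.28 ± 2.80 CPM was 20.7% of the WT mean of 20.7 ± 19.2 CPM, again with an exact permutation p of 0.0286 (n = 4 per group). Without WT replicate 8 the 12-week WT mean was 11.2 CPM and the KO share 38.2%. In the model over all genes the log2 fold change was -2.31 ± 0.69 at 6 weeks (adjusted p = 0.21) and -2.22 ± 0.69 at 12 weeks (adjusted p = 0.11), so Ercc1 missed the threshold there.

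**Figure D1:**
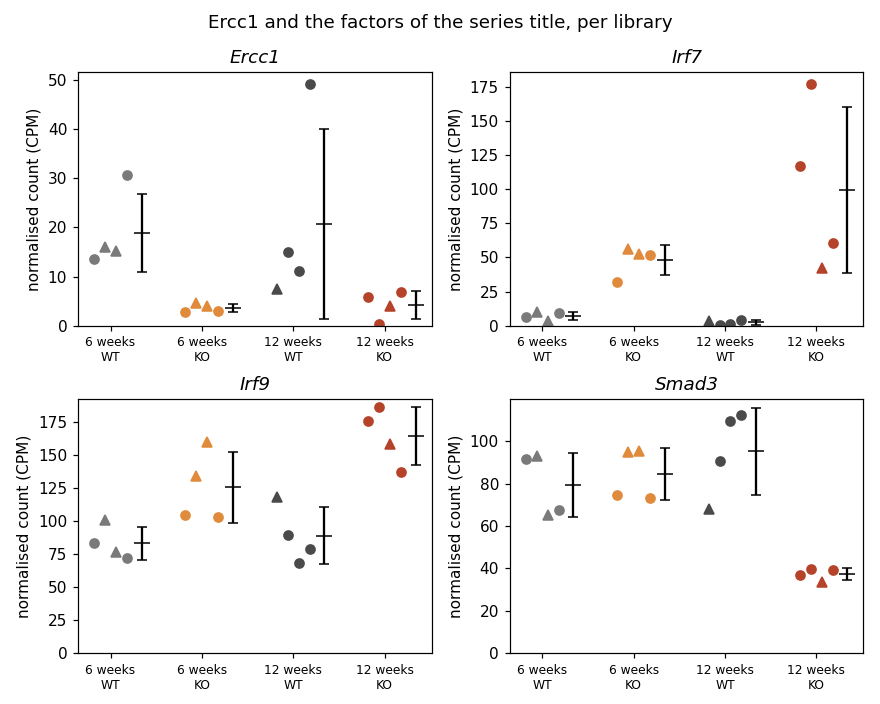
CPM of Ercc1, Irf7, Irf9 and Smad3 in each of the 16 libraries by group, with circles for male and triangles for female libraries and bars for the mean and SD of 4 libraries. Ercc1 was lower in all KO libraries than in the WT libraries of their age, Irf7 was higher, and Smad3 fell from a mean of 95.2 CPM in 12-week WT to 37.4 CPM in 12-week KO.

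Sex labels were compared with Xist, the RNA that silences an X chromosome in females, and with the Y genes Ddx3y, Eif2s3y, Kdm5d and Uty, in CPM on the unscaled library sizes. All 6 female libraries had at least 389 CPM of Xist and at most 10.1 CPM of the summed Y genes. In 9 of the 10 male libraries Xist reached at most 11.4 CPM and the Y sum lay between 259 and 421 CPM. The male-labelled 12-week WT replicate 5_6 had both, with 349.6 CPM of Xist and 112.6 CPM of the Y genes.

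**Figure D2:**
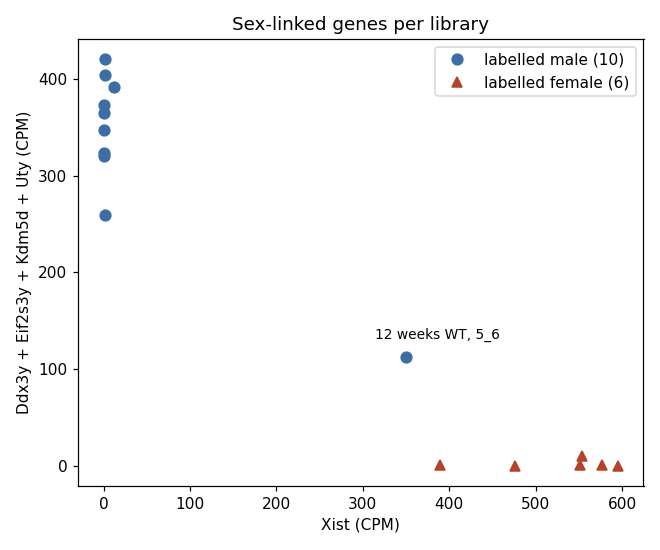
Xist against the summed Y genes Ddx3y, Eif2s3y, Kdm5d and Uty in CPM, with 1 point per library. The 12-week WT replicate 5_6 lies between both sexes, with 349.6 CPM of Xist and 112.6 CPM of the Y genes.

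The comparison of KO with WT at 6 weeks asked how the Ercc1 KO genotype changed microglia at the younger age. Genes of inflammation, interferon response and antigen presentation were higher in KO. Il1rn (ENSMUSG00000026981), the antagonist of the interleukin 1 receptor, had no count in any WT library and 21.9 ± 2.80 CPM (SD, n = 4) in KO, at least 284-fold higher. Apoe, the lipid carrier that marks activated microglia, rose from 989 ± 242 to 3785 ± 248 CPM. Irf7 (ENSMUSG00000025498), a central transcription factor of the interferon response, rose from 7.12 ± 2.94 to 48.0 ± 10.8 CPM, a log2 change of 2.77 ± 0.56 (adjusted p = 0.027).

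At 6 weeks 149 of 17090 genes passed the threshold in edgeR, 136 higher and 13 lower in KO, and 1250 had an unadjusted p under 0.05 where chance gives 854.5. Groups did not overlap for 1346 of the tested genes, and 2.86% would do so by chance. Besides Il1rn, the largest rises were those of Cxcl10, an interferon-induced chemokine, Cd69, an early activation antigen of leukocytes, Zbp1, a sensor of left-handed nucleic acids, Ifi206, an interferon-inducible gene, Lgals3, which encodes galectin 3, and the chemokines Cxcl13 and Ccl8. Cxcl10 and Cd69 had no count in WT and were at least 125-fold and at least 90.2-fold higher in KO. Zbp1 rose by 6.66 ± 1.25 on the log2 scale (adjusted p = 0.017), Lgals3 by 6.06 ± 0.93 (0.0028) and Cxcl13 by 6.03 ± 1.20 (0.037). The KO to WT ratio was 78.8 for Ifi206 (interval 25.2 to 763) and 65.6 for Ccl8 (17.9 to 259), each with 1 to 3 counts in WT. C5ar2, a receptor for the complement fragment C5a, had the largest fall, from 51.2 ± 22.4 to 1.58 ± 0.812 CPM. Gpr165, an orphan receptor, changed by -1.47 ± 0.31 on the log2 scale, the ubiquitin ligase gene Trim65 by -1.42 ± 0.29 and the vesicle trafficking gene Lrba by -1.24 ± 0.22. Csmd3, Ankrd44, Nav3 and Ecscr fell less, with log2 changes between -0.82 and -0.52. As the naming rule requires, all 4 KO libraries lay on the same side of all 4 WT libraries for each of these genes. Irf9 (ENSMUSG00000002325), a partner of the STAT proteins in interferon signalling, had a log2 change of 0.58 ± 0.16 (adjusted p = 0.15), from 82.9 to 125 CPM. Smad3 (ENSMUSG00000032402), a mediator of TGF-beta signalling, had 0.10 ± 0.18 (adjusted p = 1).

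The count at 6 weeks depended on each library: without WT replicates 1, 2, 3 and 4 it was 88, 94, 85 and 88 genes, and without KO replicates 1, 2, 3 and 4 it was 87, 99, 82 and 100 genes. The number of lower genes, 13 with all libraries, was 6, 10, 1 and 4 without WT replicates 1, 2, 3 and 4, and 1, 8, 2 and 5 without KO replicates 1, 2, 3 and 4. Of the 8 named falls none passed in every refit: Lrba passed in 7 of 8, Trim65 in 3, Nav3 and Ecscr in 2, and C5ar2, Gpr165, Csmd3 and Ankrd44 in 1. Of 54 called genes followed by name, 28 passed in all 8 refits, 6 passed in none (Ccl8, Cd69, Cxcl13, Ifi206, Nusap1 and Rps3), and Irf7 passed in 1, with adjusted p from 0.037 to 0.11. Ccnb2 passed in 5 of 8, Zbp1 in 4, Top2a, H2-M3, H2-DMa, P2ry12 and mt-Nd1 in 3, Cxcl10 in 2, and mt-Nd4, mt-Cytb and Rb1 in 1. The fitted log2 change was 10.67 for Zbp1 without WT replicate 2 and 9.29 for Cxcl13 without WT replicate 4, the libraries that held all their WT counts, and such fitted values depend on the prior. For Ifi206 and Ccl8 no WT count was left without WT replicates 2 and 3. The log2 change was 7.84 for Ccnb2 without WT replicate 4, 6.15 for Ccl5 without WT replicate 3 and -5.63 for C5ar2 without KO replicate 2.

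Primed and interferon genes had the largest median changes among lists past the set test at 6 weeks. Of 21 tested genes of primed or disease-associated microglia, 14 rose and 0 fell (19 adjusted over the list alone), with a median log2 change of 2.36 and a camera adjusted p of 4.09e-67. Among them Lpl, a lipoprotein lipase, rose by 2.92 ± 0.24, Apoe by 1.94 ± 0.18, Cst7, a protease inhibitor, by 3.45 ± 0.39 and Cd63, a protein of late endosomes, by 1.29 ± 0.15. Of 43 interferon-stimulated genes 16 rose and 0 fell (32 adjusted over the list alone), with a median of 2.76, or 2.71 with genes at 0 set to their bound, and an adjusted p of 3.83e-65. Rtp4 rose by 2.51 ± 0.29, Lgals3bp by 2.24 ± 0.29, Ifitm3, which restricts virus entry, by 3.73 ± 0.49 and Ifi27l2a by 4.57 ± 0.63. Markers of border-associated macrophages, the macrophages of brain membranes and vessels, moved in the same direction, and 1 of 14, Ccl8, rose (4 adjusted over the list alone, median 1.70, adjusted p = 2.82e-08). Markers of monocytes did so as well, with 0 of 7 past the threshold over all genes and 1 over the list alone (median 1.51, adjusted p = 0.0152).

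Antigen presentation, inflammation, lysosome and cell cycle genes rose as groups at 6 weeks. Of 18 MHC class I genes 4 rose (5 adjusted over the list alone, median 0.43, adjusted p = 7.76e-17), namely H2-D1 by 1.79 ± 0.17, H2-K1 by 1.73 ± 0.17, B2m by 0.98 ± 0.12 and H2-M3 by 1.05 ± 0.20. Of 10 MHC class II genes 4 rose (7 adjusted over the list alone, median 0.90, adjusted p = 5.44e-23), among them the invariant chain gene Cd74 by 2.26 ± 0.20, H2-Ab1 by 2.02 ± 0.34 and H2-DMa by 0.78 ± 0.15. Of 25 inflammatory genes 9 rose (13 adjusted over the list alone, median 0.91, adjusted p = 3.93e-33), with the chemokines Ccl4 by 2.35 ± 0.23, Ccl12 by 3.19 ± 0.37 and Cxcl16 by 2.19 ± 0.28. Of 35 proliferation genes 3 rose (7 adjusted over the list alone, median 1.44, adjusted p = 1.71e-19): Ccnb2, a mitotic cyclin, by 5.39 ± 1.03, Top2a, a topoisomerase, by 2.29 ± 0.45, and the spindle gene Nusap1 by 3.01 ± 0.65. Of 28 lysosome genes 8 rose (17 adjusted over the list alone, median 0.34, adjusted p = 7.61e-25), led by the cathepsins Ctsb (0.88 ± 0.08), Ctsz (0.68 ± 0.07) and Ctsl (0.78 ± 0.11) and by the saposin precursor Psap (0.51 ± 0.07). Of 15 complement genes 1 rose, the C3a receptor gene C3ar1 by 0.95 ± 0.11 (5 adjusted over the list alone, median 0.35, adjusted p = 1.13e-06). Reads shared with close copies leave the size of the changes of the H2 genes, Cd63, Ifi206 and the Ccl chemokines uncertain.

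Genes that mark resting microglia fell as a group at 6 weeks. Of 25 homeostatic genes 0 rose and 2 fell (7 adjusted over the list alone), the purinergic receptor gene P2ry12 by a log2 change of -0.40 ± 0.08 and Nav3 by -0.58 ± 0.12, with a list median of -0.25 and a camera adjusted p of 8.66e-10. Metabolic lists shifted upward: 1 of 20 glycolysis genes rose, Pkm by 0.77 ± 0.12 (7 adjusted over the list alone, median 0.43, adjusted p = 1.31e-07). Of 19 lipid handling genes 0 passed (1 over the list alone, median 0.46, adjusted p = 0.00254), and of 20 oxidant and NRF2 genes 0 passed (3 over the list alone, median 0.30, adjusted p = 0.000231). Of 35 ribosomal protein genes 3 rose (12 adjusted over the list alone, median 0.40, adjusted p = 2.73e-10), Rplp0 by 0.82 ± 0.12, Rpl32 by 0.93 ± 0.16 and Rps3 by 0.52 ± 0.11. All 7 tested mitochondrially encoded genes had positive changes, and 4 rose (7 adjusted over the list alone, median 0.63, adjusted p = 1.67e-14), mt-Co1 by 0.71 ± 0.12, mt-Nd1 by 0.71 ± 0.14, mt-Nd4 by 0.63 ± 0.13 and mt-Cytb by 0.70 ± 0.15. None of 30 nuclear genes of oxidative phosphorylation passed over all genes and 1 did over the list alone (median 0.14, adjusted p = 0.00275). That call was lost with adjusted p = 0.116 with an estimated correlation. The T and NK cell list had 2 tested genes, of which the chemokine Ccl5, also on the inflammatory list, rose by 5.56 ± 0.81 while Klrd1, a receptor gene of NK cells, had -1.09 ± 0.87, so the upward result rests on Ccl5 (adjusted p of the list = 0.0184, and adjusted p = 0.0524 with an estimated correlation). The other lists past the set test kept that call with an estimated correlation.

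The set test did not pass for the other 14 lists at 6 weeks. The p53 list had a median of 0.17 with 0 of 27 genes past the threshold (adjusted p = 0.0894). The senescence list had 0.38 (adjusted p = 0.353), and 1 of its 9 genes fell, the retinoblastoma gene Rb1 by a log2 change of -0.41 ± 0.08. Medians and adjusted p were 0.06 and 0.835 for excision and crosslink repair, where the mean was -0.04 and the test pointed upward, 0.03 and 0.701 for TGF-beta and SMAD signalling, 0.23 and 0.567 for cholesterol synthesis, and 0.35 and 0.0817 for immediate early genes. Of the 27 transcription factors of microglia and interferon 1 rose, Irf7, with a list median of -0.00, a mean of 0.13 and an adjusted p of 0.779 upward. Among markers of other cells, medians were -0.30 for neurons, 0.07 for astrocytes, -0.14 for oligodendrocytes, -0.09 for endothelial cells with a mean of 0.07 and a test upward, -0.23 for erythroid cells, 2.69 for the 2 tested neutrophil genes and -0.04 for B cells with a mean of 0.24 and a test downward. Their adjusted p lay between 0.141 for neurons and 0.967 for endothelial cells.

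**Figure D3:**
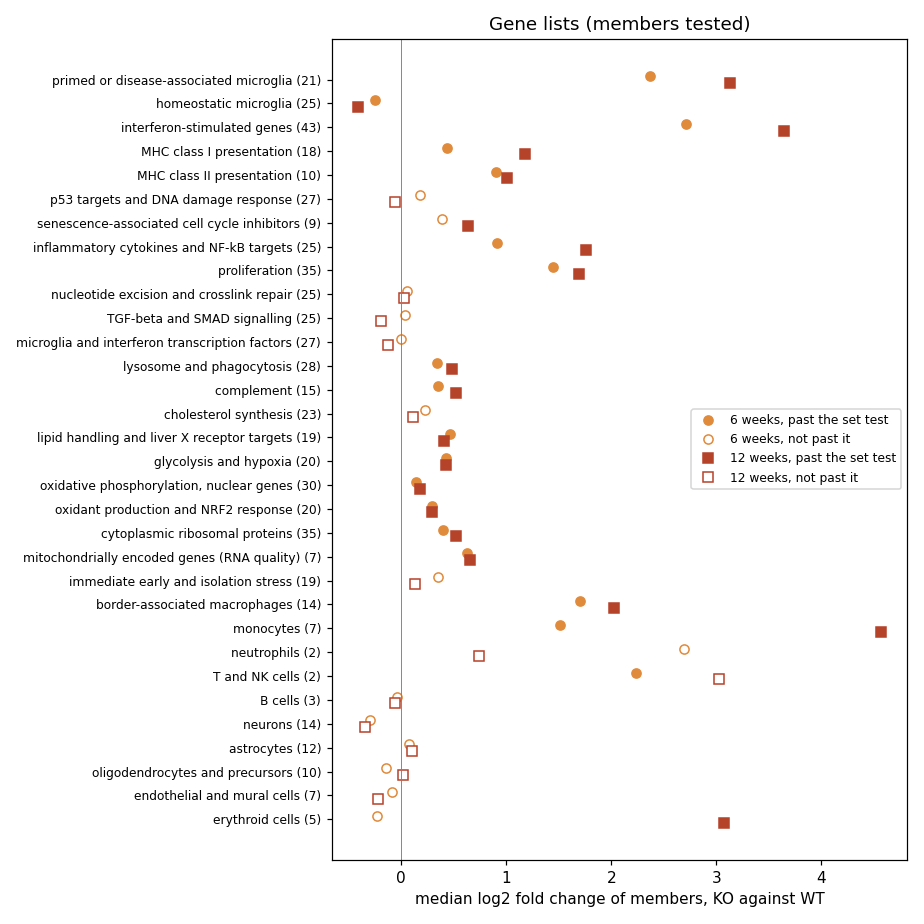
Median log2 fold change of KO against WT for 32 gene lists at 6 weeks (circles) and 12 weeks (squares), with genes at 0 set to their bound and filled points past the camera test. Primed genes had medians of 2.36 and 3.13 and homeostatic genes of -0.25 and -0.41.

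The comparison of KO with WT at 12 weeks asked the same question at the older age. Axl (ENSMUSG00000002602), a receptor kinase for dying cells, had no count in any 12-week WT library and 169 ± 48.5 CPM (SD, n = 4) in KO, at least 2940.0-fold higher. Apoe rose from 730 ± 115 to 6389 ± 1417 CPM, Irf7 from 2.43 ± 1.82 to 99.2 ± 60.8 CPM and Irf9 from 88.5 ± 21.5 to 164 ± 21.6 CPM. Smad3 fell from 95.2 ± 20.5 to 37.4 ± 2.84 CPM, and P2ry12 fell from 16862 ± 1479 to 9622 ± 763 CPM.

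At 12 weeks 510 of 17090 genes passed in edgeR, 347 higher and 163 lower in KO, and 2454 had an unadjusted p under 0.05 where chance gives 854.5. Groups did not overlap for 1402 genes, against 2.86% by chance. Irf7 changed by 5.37 ± 0.63 on the log2 scale (adjusted p = 0.00015), Irf9 by 0.92 ± 0.16 (0.0040) and Smad3 by -1.35 ± 0.19 (0.00068), each with all 4 KO libraries on the same side of all 4 WT libraries. Other large rises were those of genes without a count in WT. Cxcl13 was at least 662-fold higher, the interferon-induced synthetase gene Oas2 at least 635-fold, Rsad2, which encodes the antiviral protein viperin, at least 589-fold, and Il1rn at least 475-fold. Il12b, a subunit of interleukin 12, was at least 406-fold higher, Ifi202b, an interferon-inducible gene, at least 359-fold and Cd69 at least 350-fold. Without KO replicate 2 these bounds were 175-fold for Cxcl13, 352-fold for Rsad2, 158-fold for Il12b and 131-fold for Cd69. Without WT replicate 5_6, the deepest WT library, each bound against 12-week WT was 1.78 times lower. Rnase10 had the largest fall, with a KO to WT ratio of 0.00694 (interval 0.000794 to 0.0239). Log2 changes were -2.56 ± 0.63 for the receptor phosphatase gene Ptprz1, -2.45 ± 0.53 for the catenin gene Ctnnd2, -2.15 ± 0.32 for Gpr165, -2.12 ± 0.53 for Cpt1c, a carnitine acyltransferase of brain, and -2.10 ± 0.42 for Mypopos, an antisense gene whose value depends on the unstated strand setting. The zinc finger gene Zfp180 changed by -1.76 ± 0.39 and the Fc receptor-like gene Fcrl1 by -1.57 ± 0.22. Whether the falls named at either age arose in microglia or in RNA of other cells in the sorts was not tested. Copies of the Oas and Ifi families share reads, so the sizes for Oas2 and Ifi202b are uncertain.

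Without KO replicate 2 the count at 12 weeks was 328 genes, and without the 12-week WT replicates 3 and 8, a removal chosen after seeing the data, it was 307 genes, of which 256 were among the 510. A planned fit on the 12-week libraries alone gave 204 genes, 27 of them lower. In the fit on both ages the 163 lower genes became 90 and 101 without WT replicates 3 and 5_6, and 103, 89 and 108 without KO replicates 1, 2 and 3. Of 76 called genes followed by name 61 passed in all 8 refits that left out 1 library, and 15 were lost in at least 1. Ptprz1 and Cpt1c passed in 1 of 8, Atf3, Top2a and Flt1 in 2, C1qc, Lmnb1 and Pmaip1 in 3, Cyba and Ms4a7 in 4, Ctnnd2, Zfp180 and Mcm6 in 5, Bub1 in 6, and Il12b in 7, all but that without KO replicate 2 (adjusted p = 0.0515). Log2 changes moved by over 1.5 times in fold without WT replicate 3, to 9.37 for Ccl5, 5.69 for Cybb and 2.34 for Top2a, and without WT replicate 5_6, to 4.90 for Ms4a7, 2.86 for Pmaip1 and 7.30 for Ccl5. Without KO replicate 2 Ccl5 had 7.32, and Rnase10 had no count in KO.

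As at 6 weeks, primed and interferon genes had the largest median changes at 12 weeks among lists of more than 10 tested genes. Of 21 primed genes 15 rose (18 adjusted over the list alone, median 3.13, adjusted p = 2.63e-62), with Apoe up by 3.13 ± 0.19, Cd63 by 1.82 ± 0.15 and Lpl by 2.73 ± 0.24. Of 43 interferon-stimulated genes 31 rose (42 adjusted over the list alone, median 3.65, adjusted p = 5.65e-67), with Rtp4 up by 3.65 ± 0.30, Lgals3bp by 2.84 ± 0.29 and Ifitm3 by 4.22 ± 0.49. Of 25 homeostatic genes 0 rose and 12 fell (19 adjusted over the list alone, median -0.41, adjusted p = 1.19e-18). P2ry12 changed by -0.81 ± 0.08, P2ry13, another purinergic receptor gene, by -0.67 ± 0.08, Gpr34, a lysophospholipid receptor gene, by -0.73 ± 0.10 and the selectin ligand gene Selplg by -0.49 ± 0.07. Macrophage and monocyte markers moved with the primed genes here too. Of 14 border-associated macrophage markers 2 rose, Ccl8 by 6.98 ± 1.19 and the membrane gene Ms4a7 by 3.49 ± 0.85 (7 higher and 1 lower over the list alone, median 2.03, adjusted p = 8.88e-08). Of 7 monocyte markers 1 rose, Ms4a4c by 6.50 ± 1.25 (4 over the list alone, median 6.50, or 4.57 with genes at 0 set to their bound, adjusted p = 6.09e-05). Without WT replicate 4 the fitted values were 10.77 for Ccl8 and 9.91 for Ms4a4c.

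Antigen presentation and inflammation rose as groups at 12 weeks. Of 18 MHC class I genes 11 rose (12 adjusted over the list alone, median 1.18, adjusted p = 7.57e-30), with H2-D1 up by 2.73 ± 0.18, H2-K1 by 2.38 ± 0.18, B2m by 1.43 ± 0.12 and H2-M3 by 1.82 ± 0.20. Of 10 MHC class II genes 5 rose (9 adjusted over the list alone, median 1.01, adjusted p = 2.14e-18), with Cd74 up by 3.14 ± 0.21, H2-Ab1 by 2.96 ± 0.35 and H2-DMa by 1.09 ± 0.15. Of 25 inflammatory genes 11 rose (16 adjusted over the list alone, median 1.76, adjusted p = 1.54e-34), with Ccl4 up by 3.33 ± 0.24, Ccl12 by 4.16 ± 0.38 and Tlr2, a receptor for bacterial lipoproteins, by 1.76 ± 0.16. Of 28 lysosome genes 14 rose (17 adjusted over the list alone, median 0.48, adjusted p = 6.95e-23), with Ctsb up by 1.19 ± 0.08, Ctsz by 0.85 ± 0.07, Psap by 0.62 ± 0.07 and the progranulin gene Grn by 0.80 ± 0.10. Of 15 complement genes 4 rose (7 adjusted over the list alone, median 0.52, adjusted p = 6.09e-05), among them C3ar1 by 1.11 ± 0.11 and the C1q genes C1qb by 0.41 ± 0.07 and C1qc by 0.52 ± 0.12. Of 35 proliferation genes 3 rose (16 adjusted over the list alone, median 1.69, adjusted p = 3.42e-15). The mitotic checkpoint gene Bub1 was at least 237-fold higher, the replication gene Mcm6 rose by 1.69 ± 0.38 and Top2a by 1.74 ± 0.44.

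Genes of glycolysis, oxidant response and translation rose as groups at 12 weeks, while members of the senescence list moved both ways. Of 9 senescence-associated genes 3 rose and 1 fell, and 3 and 1 adjusted over the list alone (median 0.64, adjusted p = 0.0423, lost with adjusted p = 0.0967 with an estimated correlation). Cdkn1a, the cyclin-dependent kinase inhibitor downstream of p53, rose by 1.94 ± 0.29, the lysosomal galactosidase gene Glb1 by 0.79 ± 0.16 and the lamin gene Lmnb1, whose loss is a mark of senescent cells, by 2.31 ± 0.53. Rb1, an inhibitor of the cell cycle, changed by -0.61 ± 0.08, so 2 of the 4 called members ran against a senescent pattern. In the p53 list, which also holds Cdkn1a, 2 of 27 genes rose (4 higher and 1 lower over the list alone). The other was the apoptosis gene Pmaip1, by 2.23 ± 0.53. That list had a median of -0.06, a mean of 0.53 and an adjusted p of 0.136, in the upward direction. Of 20 glycolysis genes 4 rose (8 adjusted over the list alone, median 0.42, adjusted p = 1.13e-07), Pkm by 1.07 ± 0.12, Ldha by 0.94 ± 0.15, Hif1a by 1.06 ± 0.19 and Tpi1 by 0.84 ± 0.17. Of 20 oxidant and NRF2 genes 3 rose (6 adjusted over the list alone, median 0.29, adjusted p = 0.00171), the peroxiredoxin gene Prdx1 by 0.66 ± 0.14 and the NADPH oxidase genes Cybb by 4.83 ± 1.00 and Cyba by 0.40 ± 0.10. Of 35 ribosomal protein genes 9 rose (16 adjusted over the list alone, median 0.52, adjusted p = 6.89e-12), with Rplp0 up by 1.04 ± 0.12 and Rpl32 by 1.06 ± 0.16. Of 7 mitochondrially encoded genes 4 rose (7 adjusted over the list alone, median 0.65, adjusted p = 4.18e-11), mt-Co1 by 0.89 ± 0.12, mt-Cytb by 0.95 ± 0.15, mt-Nd4 by 0.67 ± 0.13 and mt-Nd1 by 0.64 ± 0.14.

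Further lists were less firm at 12 weeks. Of 30 nuclear oxidative phosphorylation genes 1 rose, the cytochrome oxidase gene Cox4i1 by 0.68 ± 0.11 (median 0.17, adjusted p = 0.0257, and adjusted p = 0.232 with an estimated correlation). Of 19 lipid handling genes 0 passed over all genes, and 5 were higher and 1 lower over the list alone (median 0.41, adjusted p = 0.0419, and adjusted p = 0.0634 with an estimated correlation). Of 5 erythroid markers 0 passed over all genes and 2 over the list alone (median 3.07, adjusted p = 0.0188, and adjusted p = 0.232 with an estimated correlation). Of 25 TGF-beta and SMAD genes 1 fell, Smad3 (1 higher and 2 lower over the list alone), with a median of -0.20, a mean of 0.14 and an adjusted p of 0.173 in the downward direction. Of 27 transcription factors 2 rose, Irf7 and Irf9, and 2 fell, Smad3 and the macrophage factor Maf by a log2 change of -0.64 ± 0.12, with a median of -0.13, a mean of 0.32 and an adjusted p of 0.707 downward. Medians and adjusted p were 0.03 and 0.707 for excision and crosslink repair with a mean of -0.10 and a test downward, and 0.11 and 0.713 for cholesterol synthesis with a mean of -0.06 and a test upward. For immediate early genes they were 0.13 and 0.117, and 1 of 19 rose, Atf3, a stress-induced factor, by 1.63 ± 0.42. Ccl5 rose by 7.92 ± 0.92 and Klrd1 had -1.87 ± 0.90 (adjusted p = 0.36), while the T and NK cell list had a median of 3.02 and an adjusted p of 0.0885. Flt1, a receptor for vascular growth factor, was at least 119-fold higher with 6.85 ± 6.97 CPM in KO (at least 74.9-fold without KO replicate 2), while the endothelial list had a median of -0.22, a mean of 1.12 and an adjusted p of 0.707 upward. Medians were 0.74 for neutrophils, -0.06 for B cells with a mean of 0.02 and a test downward, -0.34 for neurons, 0.10 for astrocytes and 0.01 for oligodendrocytes, with adjusted p from 0.0931 for neurons to 0.892 for oligodendrocytes.

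Genes that differed at 6 weeks were for the most part those that differed at 12 weeks. Of the 136 genes higher at 6 weeks 128 were also higher at 12 weeks, where independent lists would share 2.76, and of the 13 lower genes 7 were also lower, where 0.124 would be shared. None was called in opposite directions. Both comparisons came from the same fit with a shared spread per gene, so their lists are not fully independent. No overlap was made from separate fits of each age. Of the 149 genes, 148 had the same sign at 12 weeks and 109 had a larger change there. Across genes, which are not independent replicates, log2 changes at both ages correlated with Pearson's r of 0.297 and Spearman's rho of 0.257 over 17090 genes. Over the 11201 genes with a mean of at least 5 CPM they were 0.604 and 0.362. The 135 shared genes became 80, 83, 80 and 80 without 6-week WT replicates 1, 2, 3 and 4, and 83 and 76 without 6-week KO replicates 1 and 3. The 7 shared lower genes became 1, 5, 0 and 2 without 6-week WT replicates 1, 2, 3 and 4, and 1, 3, 0 and 2 without 6-week KO replicates 1, 2, 3 and 4, so the overlap rests on the higher genes.

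**Figure D4:**
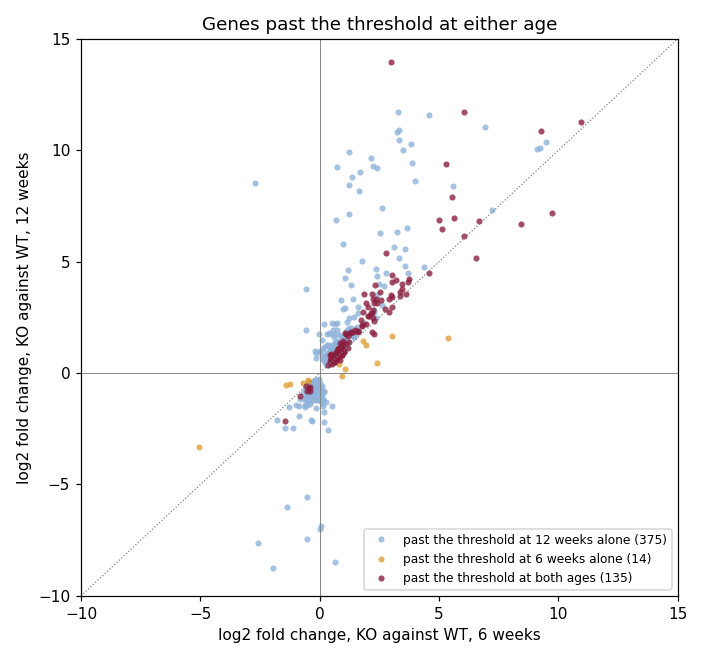
Log2 fold change of KO against WT at 6 weeks (horizontal) and 12 weeks (vertical) for genes past the threshold at either age, where values of genes with a group at 0 are fitted and depend on the prior. Of the 149 genes called at 6 weeks, 148 had the same sign at 12 weeks.

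The comparison of 12 with 6 weeks in KO asked what changed with age in that genotype. Cd164, a sialomucin of the cell surface, fell from 1063 ± 46.4 to 684 ± 49.9 CPM (SD, n = 4), a log2 change of -0.62 ± 0.07 (adjusted p = 0.0019). Both Cx3cr1, the fractalkine receptor gene of microglia, and P2ry13 fell, by -0.57 ± 0.08 and -0.55 ± 0.08 on the log2 scale (adjusted p = 0.035 for each). The mitochondrial gene mt-Co1 rose by 0.76 ± 0.12 (adjusted p = 0.046). In each of these 4 genes all libraries of 1 age lay on the same side of those of the other, as they did for Smad3, which had -1.20 ± 0.19 and missed the threshold (adjusted p = 0.054). Irf7 had 1.00 ± 0.55 (0.67), Irf9 0.50 ± 0.16 (0.35) and Ercc1 0.12 ± 0.69 (0.99).

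These 4 genes, 1 higher and 3 lower, were all that passed of 17090 in edgeR, with 1504 at an unadjusted p under 0.05, 1122 without overlap (2.86% by chance) and 270 past the threshold in DESeq2. The call of Cd164 stood without any 1 of the 8 libraries, while P2ry13 passed in 2 of these refits, Cx3cr1 in 1 and mt-Co1 in 0 (adjusted p from 0.0665 to 0.150). The count was 1 without 6-week KO replicate 1 or without 12-week KO replicate 1, 2 or 4, and 2 without 6-week KO replicate 4.

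Homeostatic genes fell as a group with age in KO: 2 of 25, Cx3cr1 and P2ry13, fell over all genes and 15 over the list alone (median -0.30, adjusted p = 4.27e-14). Primed genes rose as a group (median 0.38, 6 of 21 over the list alone, adjusted p = 4.78e-05), and so did ribosomal protein genes (median 0.29, 4 of 35 over the list alone, adjusted p = 4.98e-10). These 3 lists kept the call with an estimated correlation. Another 8 lists passed with the preset correlation alone. Adjusted p with an estimated correlation was 0.125 for interferon-stimulated genes (median 0.85), 0.148 for MHC class I (0.64, with 10 of 18 genes over the list alone) and 0.0576 for MHC class II (0.30). It was 0.150 for inflammatory genes (0.43), 0.303 for proliferation (0.27), 0.101 for oxidative phosphorylation (0.30), 0.0576 for mitochondrially encoded genes (0.53, with all 7 over the list alone) and 0.371 for erythroid markers (1.92).

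The same comparison in WT asked what changed between these ages in control mice. Axl fell from 9.52 ± 4.67 CPM (SD, n = 4) at 6 weeks to no count in any library at 12 weeks, at least 165-fold lower (92.8-fold without the 12-week replicate 5_6). Slc7a8, a transporter of neutral amino acids, fell from 476 ± 50.5 to 231 ± 32.3 CPM, a log2 change of -1.04 ± 0.13 (adjusted p = 0.0059). In both genes all 4 libraries at 12 weeks lay below all 4 at 6 weeks. Log2 changes were 0.02 ± 0.67 for Ercc1 (adjusted p = 1), -1.60 ± 0.58 for Irf7 (0.52), 0.16 ± 0.16 for Irf9 (0.95) and 0.25 ± 0.19 for Smad3 (0.88).

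These 2 genes were the only calls of 17090 in edgeR, 0 of them higher, with 1271 at an unadjusted p under 0.05, 907 without overlap (2.86% by chance) and 150 past the threshold in DESeq2. The count was 1, Axl, without 6-week WT replicate 4, and 4 without 12-week WT replicate 4, where Cmtm6 and Tnfrsf23 joined them, genes named after their values were seen. By the set test genes of oxidative phosphorylation (median 0.31), ribosomal proteins (0.22) and the mitochondrial genome (0.52, with 6 of 7 over the list alone) were higher and oligodendrocyte markers lower (-0.66) at 12 weeks, with adjusted p of 8.42e-05, 0.000636, 1.12e-08 and 0.0292. None kept the call, with adjusted p = 0.146 with an estimated correlation for each. The 4 lists became 9, 7, 7 and 7 without 6-week WT replicates 1 and 3 and 12-week WT replicates 4 and 8.

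Whether the genotype effect itself differed between ages was tested as an interaction. Axl was the only gene past the threshold, with a larger KO effect at 12 weeks (adjusted p = 0.00057). It stood at 9.52 ± 4.67 CPM in WT and 70.7 ± 23.9 CPM in KO at 6 weeks, and at 0 in WT and 169 ± 48.5 CPM in KO at 12 weeks (SD, n = 4). The call stood without any 1 of the 16 libraries. The difference in log2 changes was -1.45 ± 0.26 for Smad3 (adjusted p = 0.33), 2.60 ± 0.78 for Irf7 (0.85), 0.34 ± 0.22 for Irf9 (1) and 0.09 ± 0.92 for Ercc1 (1). So after adjustment over all genes the fall of Smad3 at 12 weeks was not shown to differ from its value at 6 weeks. This does not show equal effects, since the model recovered 16.7% of planted 4-fold changes for the interaction in simulated data. The difference for Smad3 kept its sign in all 16 refits without 1 library and passed the threshold in 0. Without 12-week WT replicate 3 the count was 2, Axl and Gpx3, the latter named after its values were seen, with 810 genes at an unadjusted p under 0.05 in the full fit, where chance gives 854.5, and 53 past the threshold in DESeq2.

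Among lists, primed genes had a larger genotype effect at 12 weeks (median difference 0.51, 1 of 21 over all genes and 2 over the list alone, adjusted p = 7.19e-07), and they kept that call with an estimated correlation (adjusted p = 0.0407). The others past the test lost it. Adjusted p with an estimated correlation was 0.327 for interferon-stimulated genes (median difference 0.60), 0.287 for MHC class I (0.53), 0.294 for inflammatory genes (0.65), 0.327 for homeostatic genes (-0.21), 0.121 for monocyte markers (2.84) and 0.354 for erythroid markers (3.31).

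Because long genes offer a larger target for transcription-blocking DNA lesions, the relation of expression to gene length was compared between genotypes. For each library the Spearman correlation with gene length was taken over 17064 genes, after subtracting the mean of its age. At 12 weeks it averaged -0.0436 ± 0.0227 (SD, n = 4) in KO and 0.0536 ± 0.0211 in WT, with an exact permutation p of 0.0286, the smallest of 70 regroupings. At 6 weeks it averaged -0.0306 ± 0.0296 in KO and 0.0337 ± 0.0433 in WT, with an exact permutation p of 0.0571. Among 11192 genes with a mean of at least 5 CPM the exact permutation p was 0.0286 at both ages (n = 4 per group), with KO minus WT differences of -0.132 at 6 weeks and -0.142 at 12 weeks. From the 10% shortest to the 10% longest of these genes the median log2 change of KO against WT went from 0.10 to -0.12 at 6 weeks and from 0.09 to -0.19 at 12 weeks.

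**Figure D5:**
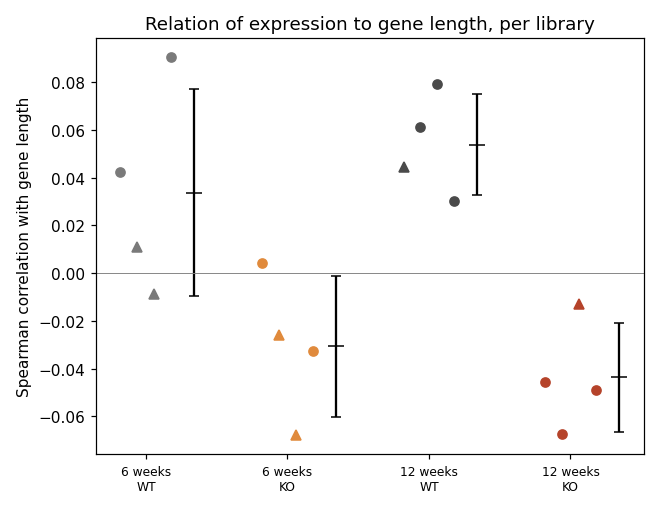
Spearman correlation of expression with gene length in each of the 16 libraries, with circles for male and triangles for female libraries and bars for the mean and SD of 4 libraries. At 12 weeks all KO libraries lie below all WT libraries, with means of -0.0436 and 0.0536.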

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

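The tests of isolation stress, of border-associated macrophages, of other leukocytes and of the mixed-sex library were chosen only after the result was seen.

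Axl and 7 gene lists differed in the size of the genotype effect between 6 and 12 weeks. For Axl the interaction had an adjusted p of 0.00057. For lists the camera adjusted p was 7.19e-07 for primed genes, 5.27e-05 for homeostatic genes, 1.19e-07 for interferon-stimulated genes, 1.19e-07 for MHC class I, 0.000155 for inflammatory genes, 0.00705 for monocyte markers and 0.00397 for erythroid markers. Of these, the primed list alone stayed past the threshold with an estimated correlation.

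Primed genes were higher in KO together with markers of border-associated macrophages and monocytes, so cells of other types may have entered the KO sorts. If border-associated macrophages were the source, their own markers would have to rise at least as far as the called primed genes. The median of called primed genes exceeded that of these markers by 0.793 on the log2 scale at 6 weeks (interval -0.66 to 1.72) and by 1.53 at 12 weeks (-0.36 to 3.16), and the intervals include 0. These intervals come from 10000 resamplings of genes, so they treat genes as independent and leave out the spread between animals. The primed genes were limited to those called higher in these data, which raises their median, while all tested markers were used. None of the 14 markers is on another list, 3 have a mean of at least 5 CPM in WT, and the gate on intermediate CD45 would remove cells with high CD45. At each age 13 of the 14 markers had positive changes. Of the 3 most abundant, Mrc1 went from 25.8 to 66.9 CPM at 6 weeks and from 13.5 to 57.1 CPM at 12 weeks, F13a1 from 23.2 to 63.4 and from 11.8 to 44.9 CPM, and Stab1 from 229 to 184 and from 216 to 142 CPM, none of them past the threshold. A change of state in microglia and a larger share of these macrophages cannot be told apart, since activated microglia can also express such markers and no single-cell measurement is present.

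For monocytes, neutrophils and lymphocytes the same difference was 1.21 at 6 weeks (interval -0.42 to 2.90) and 2.37 at 12 weeks (-1.99 to 4.16), which leaves a larger share of these cells open as a candidate source. Of the markers tested, 1 of 7 for monocytes, 1 of 2 for neutrophils, 1 of 2 for T and NK cells and 2 of 3 for B cells have a mean of at least 5 CPM in WT, and Ccl5 is also on the inflammatory list. From WT to KO Ccr2 went from 6.06 to 12.6 CPM at 6 weeks and from 4.14 to 9.85 CPM at 12 weeks. At the same ages Csf3r went from 536 to 571 and from 356 to 470 CPM. Ighm went from 1107 to 1042 and from 1001 to 959 CPM. Csf3r and Ighm were high in WT, so they cannot show a small added share of such cells. Of the 14 markers 10 had positive changes at 6 weeks and 11 at 12 weeks. Some less abundant markers rose further. Ms4a4c went from 1.27 to 15.99 and from 0.359 to 31.06 CPM, and Ccl5 from 1.09 to 50.03 and from 0.548 to 103.8 CPM. Klrd1 went the other way, from 4.78 to 2.24 and from 7.01 to 1.99 CPM. The gate without Ly6c would remove Ly6c-positive monocytes and neutrophils, and its demand for high CD11b and intermediate CD45 would remove most B and T cells.

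Ribosomal protein genes and mitochondrially encoded genes were higher in KO at both ages, and transcript length or GC bias of the libraries may raise such short transcripts. The median of ribosomal protein genes lay above 99.98% of lists matched for length, GC content and level at 6 weeks, and above 100% at 12 weeks. For ribosomal protein genes this argues against such bias as the whole cause. The matched lists were drawn gene by gene, so these shares treat genes as independent and leave out the spread between animals. For nuclear oxidative phosphorylation genes the median lay above 90.94% at 6 weeks and 97.05% at 12 weeks, inside the matched range, so that bias stays open for them. Mitochondrially encoded genes were not compared with matched lists, so it stays open for them too. Isolation stress of the KO cells cannot be told apart from a genotype effect, because the immediate early list had an adjusted p of 0.0817 at 6 weeks and 0.117 at 12 weeks and genotype and handling share the same libraries. Genotype stays among the open explanations.

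The male-labelled 12-week WT replicate 5_6 had Xist at 349.6 CPM, far above the other male libraries, and its label carries 2 numbers without a statement of pooling. A candidate explanation is material of a male and of a female animal in 1 library: the share of female material implied by Xist was 0.666 and that of male material implied by Y genes was 0.313, which add up to 0.979. Kdm5d goes against a simple mixture, with 0 counts in this library and 13.7 to 49.8 CPM in the other male libraries. A female library labelled male is excluded by the summed Y genes at 112.6 CPM, where female libraries reached at most 10.1 CPM. No biological explanation was tested.

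The female-labelled 12-week KO replicate 3 had summed Y genes at 10.1 CPM, from 41 counts of Ddx3y and 39 counts of Eif2s3y with 0 of Kdm5d and Uty, beside 554 CPM of Xist.

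In 36 of 408 groups of 4 libraries 1 library lay far from the others, with a gap to the next value beyond Dixon's critical share of the range, where chance at 5% gives 20.4. Genes were tested on log2 of CPM plus 1. That chance number assumes normal values, which genes near 0 do not have. Wherever the gap was 1.00, the other libraries of the group had no count and the distant one had between 0.213 and 0.728 CPM. The gap was 1.00 of the range for Zbp1 in 12-week WT replicate 5_6 and in 6-week WT replicate 2, for Ifi206 in 6-week WT replicate 2, for Cxcl13 and Bub1 in 6-week WT replicate 4, for Ccl8 in 12-week WT replicate 4 and 6-week WT replicate 3, and for Rnase10 in 12-week KO replicate 2. In 6-week WT it was 0.835 for Cd63 and 0.846 for Flt1 (replicate 2), 0.834 for Cx3cr1, 0.837 for Ccnb2, 0.82904 for Hif1a and 0.844 for Ifi202b (replicate 4), and 0.909 for Lrba and 0.903 for Pmaip1 (replicate 1). In 6-week KO it was 0.859 for Irf7 (replicate 1), 0.850 for Ccl8 (replicate 2), 0.866 for C3ar1 and 0.853 for Rnase10 (replicate 3), and 0.882 for mt-Cytb, 0.887 for Il12b, 0.873 for Zfp180, 0.930 for Fcrl1 and 0.906 for the mitochondrial share (replicate 4). In 12-week WT it was 0.854 for Ifi206 and 0.972 for H2-K1 (replicate 3), 0.879 for Ms4a4c (replicate 4), 0.878 for the total count (replicate 5_6) and 0.983 for mt-Nd1 (replicate 8). In 12-week KO it was 0.922 for Rpl32, 0.844 for Il12b, 0.882 for P2ry13 and 0.831 for Mcm6 (replicate 2), and 0.903 for Pkm and 0.876 for Hif1a (replicate 4).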

How the results depend on the processing

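The halfway sex code, the removal of 12-week WT replicates 3 and 8, single libraries left out of the gene length relation, of the lower bounds and of the Ercc1 share, and the alternatives carried to the overlap were chosen only after the result was seen. Counts are given for KO against WT at 6 weeks, at 12 weeks, 12 against 6 weeks in KO, in WT, and the interaction, which were 149, 510, 4, 2 and 1, with 135 genes shared by both ages. DESeq2 size factors within edgeR gave 151, 505, 4, 2 and 1 with 137 shared, and thinning gave 141, 533, 5, 2 and 1 with 128 shared. DESeq2 with its own test gave 366, 1157, 270, 150 and 53 with 293 shared, and all genes called in edgeR were among them; the cause was not tested. Without a filter on low counts the numbers were 353, 1073, 204, 194 and 132 with 262 shared, and 132, 437, 4, 2 and 1 of the original calls were kept; the cause was not tested. Male libraries alone gave 32, 238, 0, 1 and 1 with 30 shared, with fewer samples. A minimum fold of 1.5 gave 44, 138, 0, 1 and 1 with 43 shared, being a stricter test. In that order, 1 and 0 of the 6-week genes and 53 and 10 of the 12-week genes were lower in KO. Fitting the compared libraries alone, with fewer samples to estimate the spread, gave 166 genes at 6 weeks and 204 (27 lower) at 12 weeks. It gave 0 and 0 for age, so Axl was not called in WT. Fewer samples do not account for both shifts, because the count rose at 6 weeks and fell at 12 weeks. The main fit uses 1 spread per gene for all groups, while replicates correlated with r of at most 0.869 at 12 weeks and at least 0.871 at 6 weeks. The fit on the compared libraries alone removes that sharing, and it gave 166 genes in place of 149 and 204 in place of 510. It also has fewer samples, so how far the shared spread raised the 510 calls cannot be told. A block on replicate number gave 114, 8, 0, 0 and 1 (Vapa in place of Axl), and 2 lists for age in WT. Only numbers 3 and 4 are shared by both genotypes at 12 weeks, and no correlation shows that numbers pair the animals. Under the block 3 uncalled log2 changes reversed: Ercc1 to -0.0631 with age in KO and to -1.03 with age in WT, and Irf9 to -0.0654 in the interaction; the cause was not tested. Without a sex term 166, 573, 16, 2 and 1 genes passed with 149 shared, and 8 lists for age in WT. With the mixed-sex library coded halfway they were 144, 501, 8, 2 and 1 with 130 shared; the cause was not tested. Leaving out 12-week WT replicates 3 and 8 gave 307 genes at 12 weeks (256 kept), 3 for age in WT and 2 for the interaction, with 120 shared.

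Leaving out 1 library at a time gave 82 to 100 genes at 6 weeks, 328 to 464 at 12 weeks, 1 to 3 for age in KO, 1 to 4 for age in WT, 1 to 2 for the interaction and 76 to 132 shared genes. Lists past the set test, 18, 19, 11, 4 and 7, ranged over 17 to 19, 17 to 20, 9 to 11, 3 to 9 and 6 to 9. With an estimated correlation they were 3, 0 and 1 for age in KO, age in WT and the interaction, and fry gave 6 and 2 for age in KO and the interaction. The log2 change of Ercc1 ranged over -0.12 to 0.47 with age in KO, -0.79 to 0.40 with age in WT and -0.18 to 0.98 in the interaction, none past the threshold. The difference in gene length correlation between KO and WT ranged over -0.0778 to -0.0461 at 6 weeks and -0.109 to -0.0879 at 12 weeks. At 6 weeks it was -0.0961 with exon length and -0.132 among genes of at least 5 CPM, both past the threshold; the cause was not tested. Among values of named genes without 1 library, 1000 kept their side of the threshold, 249 lost it and 15 reversed, all of them Ercc1 with age or in the interaction.

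Thinning to the shallowest library left each count within 1.5 times of the full data. Many changes would be missed: in simulated data with planted changes the model recovered 2.99% of 2-fold and 33.3% of 4-fold changes at 6 weeks, 17.9% and 54.5% at 12 weeks, and 4.48% and 16.7% for the interaction. Among genes of at least 5 CPM it recovered 62.9%, 70.6% and 23.4% of the 4-fold changes. These rates come from a single draw of 66 or 67 genes per fold, with other genes for each comparison. Of the 66 genes with a planted 4-fold change, 35 reached 5 CPM at 6 weeks and 51 at 12 weeks. The rates therefore do not compare the ages.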

Other observations

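None of the tests in this part was chosen only after the result was seen.

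Expression of long genes may be lower in KO libraries because lesions that stay unrepaired block transcription. The correlation of expression with gene length separated KO from WT completely at 12 weeks and not at 6 weeks, where the exact permutation p was 0.0571 (n = 4 per group). At 6 weeks KO replicates 1 to 4 had 0.00422, -0.0261, -0.0678 and -0.0328, and WT replicates 1 to 4 had 0.0423, 0.0108, -0.00873 and 0.0906. With summed exon length, and with genes of at least 5 CPM alone, the groups differed at 6 weeks by -0.0961 and -0.132, each with an exact permutation p of 0.0286, the smallest possible (n = 4 per group). The call at 6 weeks therefore depends on the genes and the length used, and a relation at both ages stays a hypothesis. Library preparation that favours short transcripts would move the values in the same direction. Whether this, RNA of other cells in the sorts or another source gave the relation was not tested.

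Chance is an unlikely source of the number of genes called between genotypes, though 1 of 35 is the smallest share the design can give. Of the 35 ways to split the 8 libraries at 6 weeks, 1, the real one, gave 149 genes, and the highest of the others gave 1. At 12 weeks 1 of 35 splits gave 510 genes, and the highest of the others gave 1. For age in KO 1 of 35 splits, the real one, gave as many as the 4 genes, and the highest of the others gave 0. This concerns the count and not each gene. With male libraries alone or a minimum fold of 1.5, 0 genes passed, and only Cd164 passed in every refit without 1 library. For age in WT chance cannot be excluded, because 2 of 35 splits gave at least the 2 genes found. The other split gave 21 genes, setting 6-week replicates 1 and 2 with 12-week replicates 3 and 4 against the rest. The source of these 21 calls was not tested. For the interaction 3 of 100 drawn splits, the real one included, gave at least the 1 gene found. These splits reassign genotype within each age and so remove the genotype effect itself, which a test of the interaction should keep. Chance therefore cannot be excluded for the interaction by them. The highest of the others gave 3 genes, more than the real split.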
